A study of Danio rerio with 36 samples.

How the data were processed

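The series held 36 one-colour arrays of adult zebrafish liver: 3 strains (AB, Tuebingen, WIK), both sexes, and 24 h with either the acetone vehicle (20 ppm) or PCB-126 at 130 ng/L, with 3 fish in each of the 12 groups. Per the file headers, the deposited scanner tables came from Feature Extraction 11.0.1.1 and held a Cy3 intensity per spot, background-subtracted and detrended, with a surrogate value for spots not above background and no scaling between arrays. The deposited series matrix held log2 values that the authors had already normalized between arrays, per the labels with limma, for about 6 in 10 probes. Of its 26270 rows 26210 carried an identifier of a scanner probe, but values under the same identifier did not follow each other (correlation 0.004 to 0.019). It was therefore used for counts of called probes and correlations between arrays, and no gene was read from it.

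Each array had 45220 spots, of which 43803 were not controls and covered 43603 probes; 50 probes had several spots, which were averaged. Spots that the scanner software called outliers were set to missing (228 values), no spot was saturated, and 17 arrays carried at least 1 quality flag of the software. The processed intensity was taken to log2 and the 75th percentile of each array was subtracted. That percentile had a median of 108 over the arrays and ran from 43.41 to 1138. The share of probes well above background ran from 31.6 to 72 percent between arrays.

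Probes were kept when well above background on all 3 arrays of at least 1 group (28241 probes, 10976 of them on every array). Gene names came from the reference tables supplied with the files (26043 probes named, 59.7%), and the probe with the highest mean over the 36 arrays stood for its gene. This left 18132 genes, 10419 of them with a gene symbol and the others under a transcript or clone identifier. Probes of the same gene followed each other with a median correlation of 0.815 over 6609 genes with several probes, against 0.026 for random pairs, and 22.9% of those genes lay under 0.5.

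Comparisons were fitted in R 4.3.3 with limma 3.58.1 as 12 group means over all 36 arrays, leaving 24 residual degrees of freedom. All p values are from limma's moderated test, adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The 13 comparisons were exposure in all fish, in each strain and in each sex, males against females and each strain pair in vehicle fish, and the interactions of sex with exposure, strain with exposure and strain with sex. Fold changes are log2 with their standard errors, and averages over strata weight each group equally.

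Gene sets were 41 lists of symbols covering metabolism, stress responses and cell type markers, written before the data were examined, and tested with camera at its preset correlation of 0.01 between genes. The same lists were tested with a correlation estimated per list and with fry. Camera compares a list with the other genes, whereas fry asks only whether the genes of a list move, on balance, one way.

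Genes are named in the text by a rule fixed before the data were examined. For exposure in all fish these were the 10 highest and 10 lowest fold changes among called genes that had a symbol, were well above background on at least 50% of the arrays of both sides and kept their sign in all 6 strata. The same rule gave 10 and 10 genes for sex, 6 and 6 for each strain pair, 5 and 5 for exposure in a strain or sex, and the 6 smallest p values for interactions. Genes seen on all arrays of one side and none of the other were taken by their lower bound, 5 per direction. Every measured gene of the aryl hydrocarbon receptor response list was tabulated for every exposure comparison, with up to 4 members of each other list by p value, and genes named outside the rule are said to be so.

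The model was also tried with other scalings (quantile normalization, median centring, and a normexp background model followed by either scaling), other probe filters and other ways to choose a probe, array weights, a minimum fold change, scan day or slide in the model, the authors' matrix, and each array left out in turn. The background model used median pixel intensities because the mean ones were absent. Slide here means the arrays that shared a scan time in the file headers, and slide barcodes were not used to define it. The closing section gives their effect. Calling was tested on simulated data with the observed spread per gene, independent normal noise and 200 of 18132 genes changed by a log2 of 1. This recovered 87 of the 200 for exposure in all fish, 38 in females, 29 in males, 15 in AB, 14 in Tuebingen and 1 in WIK, so most changes of that size within a single strain went uncalled.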

Results

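Livers of PCB-126-exposed fish had more transcript of the clock-linked repressor nfil3-5 (log2 fold change 2.09 ± 0.40), of the oxidative folding gene ero1a (1.72 ± 0.25) and of hprt1l (1.80 ± 0.32; 18 fish against 18). Of the 6 strain and sex strata, nfil3-5 and hprt1l rose in 6 and ero1a in 5 (adjusted p = 0.00995, 0.00671 and 0.00179). The erythropoietin gene epoa rose in 5 strata (adjusted p = 0.00841) and was well above background on 12 of 18 exposed and 5 of 18 vehicle arrays, so its fold has no exact size. The core clock gene bmal1a rose by 0.66 ± 0.15 and the clock output gene dbpb fell by 1.2 ± 0.24, both in all 6 strata (adjusted p = 0.0302 and 0.0137). The glycolytic aldoaa rose by 0.77 ± 0.19 (5 strata) and the co-chaperone dnajb1a by 0.77 ± 0.16 (6 strata; its other probe read 0.26), while the peroxisomal beta-oxidation gene decr2 fell by 0.81 ± 0.17 (6 strata; adjusted p = 0.0405, 0.0179 and 0.016). The canonical dioxin marker cyp1a was not called and had wide limits, at 0.02 ± 0.33 (95% interval −0.66 to 0.70, up to 1.62-fold). PCB-126 is a dioxin-like agonist of the aryl hydrocarbon receptor, and cyp1a induction is the usual readout of that receptor in fish.

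Of 18132 genes, 165 were called, 50 higher and 115 lower, and 2461 had an unadjusted p under 0.05. The median of all genes lay at −0.11, and the direction depended on scaling: median centring gave 102 higher of 199 called and a background-modelled 75th percentile scaling 8 of 58. Among genes with a symbol and 1 sign in all 6 strata, those rising most after nfil3-5 and hprt1l were mybpc2b (1.16), marveld2b (1.11), hipk3a (1.1), spag1b (1.1), acot9.2 (1.04), exorh (1.03), parn (1.00) and pde8a (0.99). Large falls under the same limits were those of cdc73 (−3.19 ± 0.63), crybb3 (−2.87 ± 0.69), rh50 (−2.86 ± 0.51), med17 (−2.77 ± 0.58), smyd1a (−2.73 ± 0.66), rab11bb (−2.41), atf7a (−2.32), stk17a (−2.27 ± 0.47) and smim10l3 (−2.27 ± 0.42). All of these kept their sign in the 6 strata, as the rule required, with adjusted p from 0.00612 to 0.0449. Within the 3 scan days with both treatments, each named fall was smallest on the second and largest on the third. With Tuebingen male PCB126 replicate 3 left out, cdc73 read −2.02, −0.45 and −6.32 and rh50 −1.75, −1.565 and −4.21. The exposed arrays of the third, AB male and Tuebingen female PCB126 replicate 3, carried quality flags and 47 and 106 outlier spots. Second probes separated these genes. The other probe of hprt1l read 1.41, whereas those of cdc73, crybb3, med17, stk17a and smim10l3 read 0.28, −0.48, 0.08, −0.20 and 0.30. Of the risers, mybpc2b, marveld2b, hipk3a, spag1b, parn and pde8a read 0.45, 0.13, 0.12, −0.02, 0.02 and 0.27 on other probes. Among called genes that fell by more than 1.5, 21 of 56 had other probes. Their median was −2.08 on the called probe and −0.10 on the others.

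**Figure D1:**
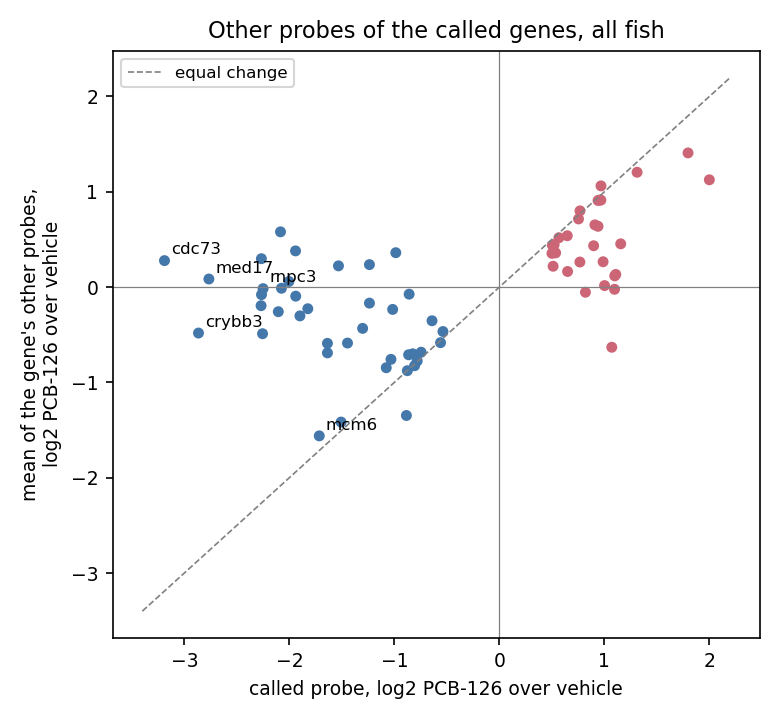
Log2 fold change on the called probe against the mean of the gene's other probes, for genes called in all exposed fish. Among genes with other probes, most of the largest falls had no counterpart on them.

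Of 36 measured genes of the unfolded protein response 30 lay higher in exposed fish (mean 0.34). The list stood above the other genes with the preset correlation (adjusted p = 2.33e-05; 0.945 with an estimated correlation, 0.504 with fry), and within the 3 scan days that held both treatments (2 strata each, Tuebingen male PCB126 replicate 3 left out) it read 0.72, −0.30 and 0.32. For the hypoxia response 18 of 30 genes lay higher, with a mean of 0.28, 3 called over all genes and 10 adjusted over the list alone (adjusted p = 0.00103; 0.945 with an estimated correlation, 0.504 with fry). Cholesterol biosynthesis genes lay lower, 22 of 25 (mean −0.42, adjusted p = 0.0258; 0.945 with an estimated correlation). In AB alone the same list was also called, but with a mean above 0 (0.305 to 0.601 under 5 other scaling settings). Within the 3 scan days it read −2.02, −0.04 and −1.64, with the −0.04 from WIK fish alone. Fatty acid oxidation genes also lay lower, 30 of 33, with decr2 as the 1 called member and 4 adjusted over the list alone (adjusted p = 0.00103; 0.945 with an estimated correlation). Within the 3 scan days that list read −0.012, −0.199 and −0.099. Proteasome genes (34 of 39 higher; 2.33e-05) and heat shock genes (13 of 21 higher; 0.00346) were also called upward, with 0.945 for both under an estimated correlation. Within the 3 scan days the proteasome list read 0.083, −0.225 and 0.075, and the heat shock list 0.197, 0.238 and 0.561. The heat shock genes hsp70l and hsp70.3 read 1.74 ± 0.48 and 1.65 without passing (adjusted p = 0.0766 and 0.0798). Of 41 lists 13 were called with the preset correlation, 5 upward and 8 downward, and none with an estimated one or with fry. Without Tuebingen male PCB126 replicate 3 the preset correlation called 9, of which 6 were upward, so most downward calls depended on that array. The means of these 13 lists kept their sign under the 4 other scalings.

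The all-fish count rested on single arrays. Leaving out Tuebingen male PCB126 replicate 3, an array with a profile unlike any other male liver, gave 369 called genes, 129 higher and 240 lower, with all 165 of the full set among them. Without that array the unfolded protein response list had 33 of 36 genes higher (adjusted p = 1.78e-05; 0.639 with an estimated correlation) and the hypoxia list 22 of 30 (0.000144; 0.0932 with an estimated correlation). Hepatocyte markers moved from an adjusted p of 0.0482 to 0.784. Counts ran from 88 without WIK female vehicle replicate 3 to 440 without Tuebingen male PCB126 replicate 2. Slide, as read from the scan times, was almost fully shared with exposure, since 1 of 12 slides held both treatments, so the 2 cannot be told apart. Scan day was partly shared with exposure, with both treatments on 3 of 7 days. Adding it to the limma model left 0 called genes, or 120 (47 higher, 73 lower) when Tuebingen male PCB126 replicate 3 was also left out. With both changes nfil3-5 read 2.52 (adjusted p = 0.0374), and the hypoxia and unfolded protein response lists had adjusted p of 0.00377 and 0.0192 with the preset correlation, the only one tried there.

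**Figure D2:**
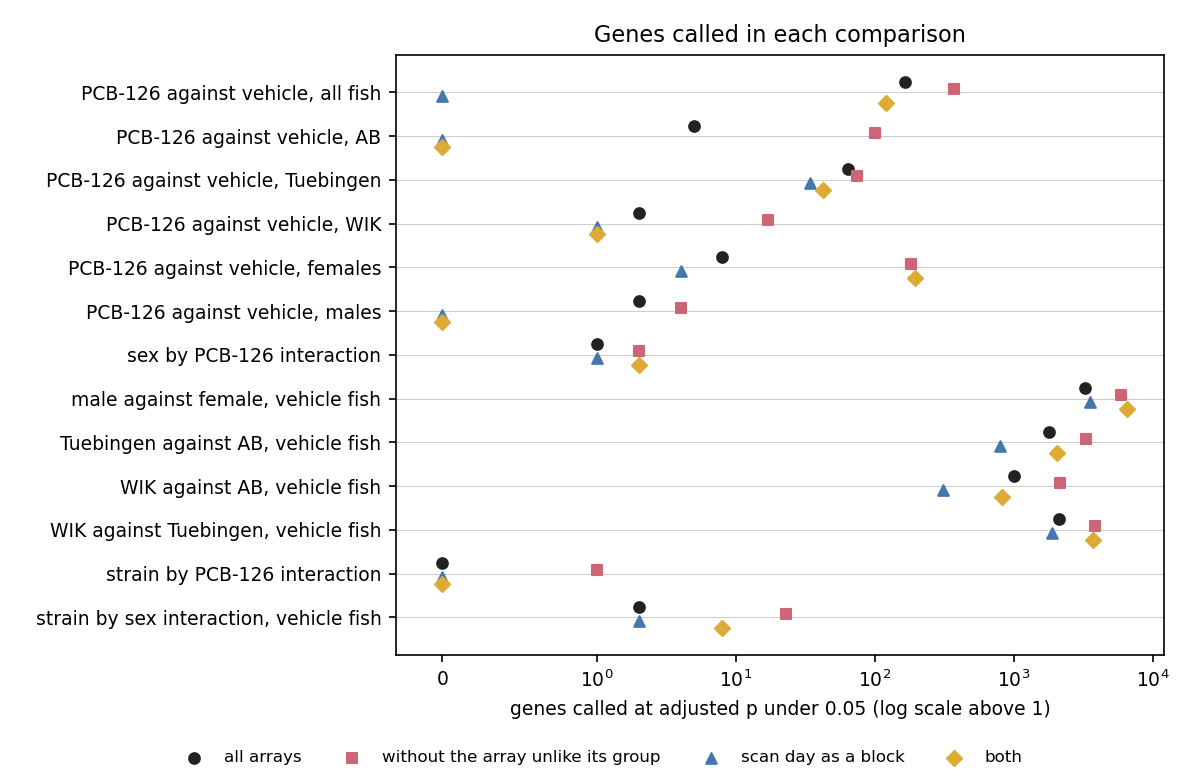
Genes called in each comparison with all arrays and without Tuebingen male PCB126 replicate 3. Exposure counts were small beside those for sex and strain.

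Transcripts of the aryl hydrocarbon receptor response were not called as a group: 4 of 15 measured genes lay higher in exposed fish and 0 were called (adjusted p = 0.456; 0.97 without Tuebingen male PCB126 replicate 3). The count of 4 is from the fit that held that array, whose hepatocyte markers averaged 2.82 against at least 7.49 elsewhere. Within the 3 scan days that held both treatments, with that array left out, the list read 0.43, −0.05 and −0.45. The cyp1a mean was 7.26 in AB female vehicle fish and 7.92 in exposed ones, 7.02 and 7.66 in Tuebingen females, and 7.12 and 7.34 in WIK females (n = 3 each). In males it was 8.41 and 8.17 in AB, 7.43 and 6.52 in Tuebingen, and 7.82 and 7.56 in WIK. That gave 0.51 ± 0.46 in females and −0.47 ± 0.46 in males, and 0.22, −0.14 and −0.02 in AB, Tuebingen and WIK (each ± 0.57). The gill and skin family member cyp1c1 read 1.08 ± 0.60 with the same sign in all 6 strata (adjusted p = 0.432), cyp1c2 0.48 ± 0.57, tiparp 0.28, cyp1d1 −0.62 and the receptor repressor ahrra −0.79. No array had cyp1b1 well above background. Without Tuebingen male PCB126 replicate 3 cyp1a read 0.32 ± 0.17 in all fish (95% interval −0.02 to 0.66, up to 1.58-fold, adjusted p = 0.367) and 0.77 ± 0.30 in Tuebingen (0.15 to 1.38, adjusted p = 0.337). In females it then read 0.505 ± 0.23 (0.03 to 0.98, adjusted p = 0.402). In males it read 0.135 ± 0.24 (−0.36 to 0.63, adjusted p = 0.941), so the male mean was no longer lower. In the same fit cyp1c1 read 1.43 ± 0.52 in all fish (0.35 to 2.51, adjusted p = 0.175) and 2.12 ± 0.76 in males (0.56 to 3.68, adjusted p = 0.417).

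**Figure D3:**
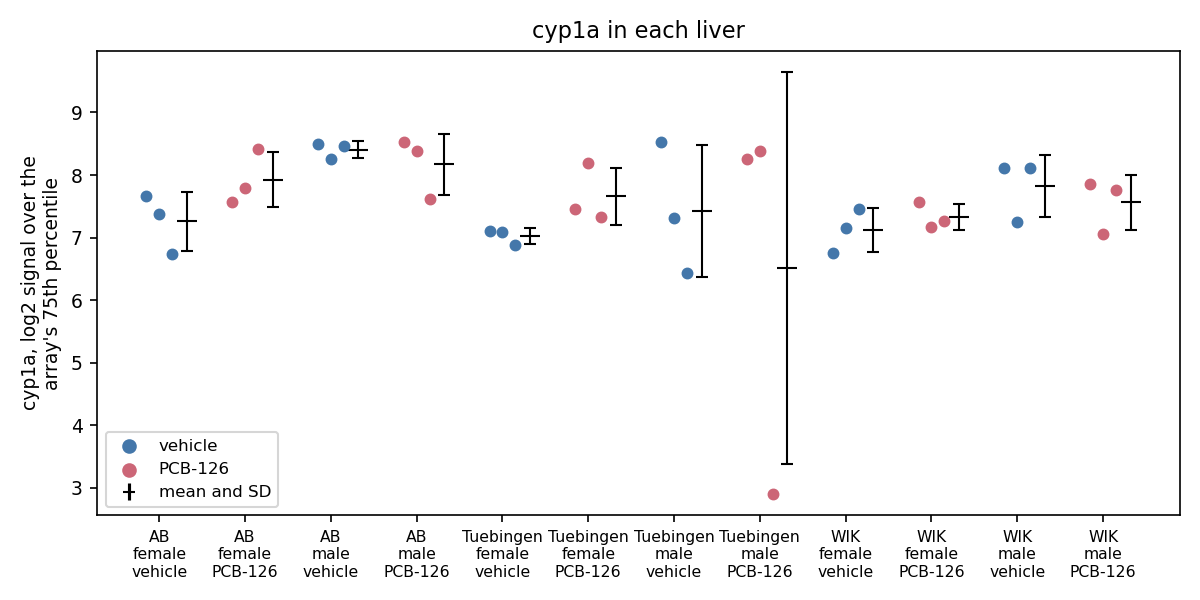
Scaled log2 intensity of cyp1a in each fish by strain, sex and treatment. The lowest point is Tuebingen male PCB126 replicate 3.

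In AB, exposed fish were higher in ero1a by 3.29 ± 0.43, in the glycolytic enolase eno1a by 2.53 ± 0.43 and in the epithelial adaptor subunit ap1m2 by 1.505 ± 0.28 (6 fish against 6, both sexes; adjusted p = 0.000561, 0.0173 and 0.0417). Other probes of eno1a and ap1m2 read 2.38 and 1.53. Genes of glycolysis and of oxidative folding are common targets of hypoxia signalling. Of the 30 hypoxia response genes 25 lay higher, with 2 called and 6 adjusted over the list alone (mean 0.85, adjusted p = 3.3e-09; 0.205 with an estimated correlation). Unfolded protein response genes were higher in 35 of 36 cases (mean 0.78, adjusted p = 5.47e-10; 0.262 with an estimated correlation) and proteasome genes in 38 of 39, with 15 passing over the list alone (mean 0.54, adjusted p = 1.02e-23; 0.205 with an estimated correlation). Replication genes lay the other way: 30 of 32 cell cycle genes lay lower (mean −1.26, adjusted p = 5.47e-10; 0.648 with an estimated correlation), with pcna at −2.20 ± 0.67 and mcm2 at −2.45, and neither passed over all genes (adjusted p for pcna 0.442). AB female vehicle replicate 3 carried egg genes (ovary marker mean 4.04) and had a cell cycle mean of 0.93, against −1.58 and −0.71 in its group mates. Those mates still lay above the exposed AB females (−2.07, −2.14 and −2.59). The list was not tested without that array.

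Respiratory chain genes lay higher in 57 of 66 cases in AB fish (adjusted p = 1.18e-07; 0.94 with an estimated correlation), and heat shock genes in 17 of 21 (adjusted p = 0.000118; 0.205 with an estimated correlation). Cholesterol biosynthesis was called with a mean above 0 (0.305 to 0.601 under 5 other scaling settings), on the opposite side to all fish. Every one of 26 pancreatic acinar markers lay lower (mean −1.19, adjusted p = 0.000279; 0.94 with an estimated correlation). Their mean varied widely between fish of the same group, so they do not count as 26 separate responses. It read 7.81, 3.78 and 4.20 in exposed AB females and 6.83, 7.47 and 4.75 in vehicle ones. In AB males it read 5.41, 2.41 and 2.475 after exposure and 3.29, 7.025 and 3.86 with vehicle. Of all genes 5 were called, 3 higher and 2 lower, with 1214 at an unadjusted p under 0.05, and none of 12 called lists held with an estimated correlation. Leaving out Tuebingen male PCB126 replicate 3, which entered AB only through the pooled spread, gave 100 genes, 42 higher and 58 lower, including all 5. Only 1 was left without AB female PCB126 replicate 2, AB male PCB126 replicate 1 or 2, or AB male vehicle replicate 1 or 3, and each of these ended the calls of eno1a and ap1m2. With scan day in the model 0 were called.

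In Tuebingen, exposed fish had more of the cytokine feedback genes cisha (4.57 ± 1.03) and socs1a (2.87 ± 0.64) and of the collagen prolyl hydroxylase gene p4ha1b (2.3 ± 0.52; 6 fish against 6, same sign in both sexes; adjusted p = 0.0413, 0.0389 and 0.0413). The erythropoietin gene epoa rose in both sexes (adjusted p = 0.0141) but was well above background on 5 of 6 exposed and 1 of 6 vehicle arrays, so its fold has no exact size. The sterol gene sc5d fell by 2.3 ± 0.52, the fatty acid elongase elovl2 by 2.93 ± 0.62 and decr2 by 1.36 ± 0.29, in both sexes (adjusted p = 0.0404, 0.0324 and 0.0324). Cholesterol biosynthesis lay lower in 23 of 25 genes, with sc5d called over all genes and 19 adjusted over the list alone (mean −1.62, adjusted p = 2.11e-09; 0.798 with an estimated correlation, 0.0184 with fry). SOCS and CISH proteins damp cytokine signalling, and cisha is a classical target of that pathway in liver. The choline transporter gene slc44a4 and bmi1b also rose (2.95 ± 0.66 and 2.07), and tuft1a (−3.70 ± 0.76), asb2b (−3.59 ± 0.72), uts2b (−3.43) and tmem79a (−3.36 ± 0.69) were among the lowest. Other probes read 3.90 for cisha and 2.99 for socs1a but −0.53 for tuft1a and 1.25 for asb2b.

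In Tuebingen 64 genes were called, 16 higher and 48 lower, with 2853 at an unadjusted p under 0.05, around a median of all genes of −0.21. These calls depended on the processing: 0 were called with normexp and the 75th percentile, 0 when only the compared groups were fitted, 0 with slide in the model and 34 with scan day, and 5 of 100 splits of the fish, the real one included, called as many (highest other 424). Without Tuebingen male PCB126 replicate 3 there were 74, of which 45 were shared. In that fit cisha stayed called (4.86, adjusted p = 0.0407), as did elovl2 (−1.99, 0.0123). The genes socs1a, slc44a4, p4ha1b, bmi1b, sc5d and decr2 moved to adjusted p of 0.0754, 0.094, 0.0678, 0.0654, 0.0944 and 0.0532. Leaving out that array reduced 19 called lists to 4. The cholesterol biosynthesis list stayed with the preset correlation alone (mean −1.50, adjusted p = 9.96e-15; 0.327 with an estimated correlation, 0.0626 with fry), while ovary markers went from 2.38 to 1.01 (adjusted p = 0.0563) and hepatocyte markers from −0.94 to −0.03 (adjusted p = 0.713). Ribosomal protein genes reversed, from 0 of 79 to 75 of 79 higher (adjusted p = 0.00503 and 1.26e-06; 0.811 with an estimated correlation). Counts ran from 3 without Tuebingen female vehicle replicate 3 to 1391 without Tuebingen male PCB126 replicate 2. Removing each of 9 of the 12 Tuebingen arrays moved it by more than 1.5 times.

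In WIK fish the mitochondrial ribosome gene mrpl36 was lower after exposure, at −1.71 ± 0.26, in 1 of 2 sexes (6 fish against 6; adjusted p = 0.00743; 0.00764 with scan day in the model). The membrane glycoprotein gene prom1a was lower in both sexes (adjusted p = 0.0123), but was well above background on 0 of 6 exposed and 5 of 6 vehicle arrays, so its fold has no exact size. With scan day in the model it still lay lower but was not called. These 2 genes lay outside the naming rule and were chosen after their values were seen. Antioxidant genes of the Nrf2 list lay higher in 20 of 27 cases, 4 of them passing over the list alone (mean 0.48, adjusted p = 5.11e-05; 0.988 with an estimated correlation). Its members with the smallest p values, txnrd3 (1.32 ± 0.28) and gclm (1.31), did not pass over all genes (adjusted p = 0.153 and 0.265). Thioredoxin reductase and glutamate-cysteine ligase supply the main thiol defences of the cell. Erythrocyte markers lay higher in 14 of 20 cases (mean 0.82, adjusted p = 0.000536; 0.988 with an estimated correlation), with slc4a1a at 2.5 (adjusted p = 0.518). Cell cycle genes lay higher in 28 of 32 (mean 0.59, adjusted p = 0.000948; 0.988 with an estimated correlation). WIK female PCB126 replicate 1 carried egg genes (ovary marker mean 4.801) and had a cell cycle mean of 1.289. Its group mates read −1.92 and −1.159, and vehicle WIK females −0.881, −1.423 and −1.231. In WIK males the cell cycle means were −0.493, −1.048 and −1.549 after exposure and −1.555, −1.82 and −1.524 with vehicle. The list was not tested without that female array. Of all genes 2 were called and 1201 had an unadjusted p under 0.05. Without Tuebingen male PCB126 replicate 3, through the pooled spread, 17 were called, 6 higher and 11 lower. In that fit txnrd3 read 1.323 (adjusted p = 0.0385), and with scan day as well 1.297 (adjusted p = 0.447).

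In exposed females ero1a rose by 2.88 ± 0.35, the aldolase gene aldocb by 1.51 ± 0.25 and hif1an, which encodes an oxygen sensor acting on hypoxia-inducible factors, by 1.31 ± 0.22, in all 3 strains (9 fish against 9; adjusted p = 0.000145, 0.00514 and 0.00514). The other probe of hif1an read 1.26 and those of aldocb 0.78. The hypoxia list, which holds ero1a but not the other two, had 23 of 30 genes higher, 1 called and 8 adjusted over the list alone (mean 0.60, adjusted p = 1.72e-06; 0.593 with an estimated correlation), and cholesterol biosynthesis had 18 of 25 lower (mean −0.49, adjusted p = 0.00137; 0.987 with an estimated correlation). The mitochondrial ribosome gene mrpl36 fell by 1.5 ± 0.21 in all 3 strains (adjusted p = 0.00104). In total 8 genes were called, 7 higher and 1 lower, with 1163 at an unadjusted p under 0.05. Scan day in the model left 4. Leaving out Tuebingen male PCB126 replicate 3 gave 181, 64 higher and 117 lower, including all 8, and with scan day as well 194.

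Exposed male livers had less rnpc3 (−2.60 ± 0.44), a gene of the minor spliceosome, and less of the transcript CN504135, in all 3 strains (9 fish against 9; adjusted p = 0.022 for both, 0.217 for both with scan day in the model). With scan day in the model rnpc3 still read −2.49. The other probe of rnpc3 read −0.12. CN504135 was well above background on 0 of 9 exposed and 6 of 9 vehicle arrays, so its fold has no exact size, and it was chosen after its values were seen. Unfolded protein response genes lay higher in 28 of 36 cases (mean 0.48, adjusted p = 2.18e-07; 0.869 with an estimated correlation), against a median of all genes of −0.20, and in 32 of 36 without Tuebingen male PCB126 replicate 3 (adjusted p = 3.12e-09; 0.536 with an estimated correlation). This response enlarges the folding capacity of the endoplasmic reticulum. Those 2 genes were the only ones called, both lower, with 2073 at an unadjusted p under 0.05, and leaving out Tuebingen male PCB126 replicate 2 gave 146. None was left without AB male PCB126 replicate 2 or 3, AB male vehicle replicate 1 or 3, Tuebingen male vehicle replicate 1 or 3, or WIK male vehicle replicate 1. Called lists went from 14 to 6 without replicate 3 of that group, with ovary markers moving from an adjusted p of 0.000162 to 0.594. Without that replicate 4 genes were called.

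The difference in response between the sexes was called for 1 transcript, TC381339 (adjusted p = 0.0199; 611 genes at an unadjusted p under 0.05), named for being the only one. It was well above background on 6 male vehicle arrays, 1 exposed male array and no female array, so its change in females has no measured size. For ero1a, aldocb and hif1an, called in females and not in males, no difference between the sexes was therefore shown. By limma's moderated F test 0 genes differed in response between strains, with 1245 at an unadjusted p under 0.05, so the calls in AB, Tuebingen and WIK do not show that the strains responded differently. The sex difference varied by strain for 2 genes, the cytochrome P450 gene cyp2k6 and the sugar transporter gene slc2a11b (adjusted p = 0.0194 and 0.0319), and for 23 without Tuebingen male PCB126 replicate 3. In vehicle fish cyp2k6 was well above background in every female (mean 4.02 in AB, 2.2 in Tuebingen, 3.54 in WIK) but in males only in Tuebingen (−2.12; 0 of 3 in AB and in WIK). Likewise slc2a11b was well above background in 3 of 3 Tuebingen males (−1.10), 1 of 3 Tuebingen females, 2 of 3 WIK females and no other vehicle fish.

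Sex differences were large, with egg yolk genes among the widest. In vehicle fish the male minus female difference was −13.88 ± 1.19 for vtg2, −11.99 ± 0.84 for vtg4, −11.68 ± 0.74 for vtg5, −10.94 ± 0.70 for vtg6 and −11.15 ± 0.53 for the yolk-associated protease gene nots (9 against 9, all 3 strains). Adjusted p was 1.11e-09 for vtg2, 1.44e-11 for vtg4, 1.78e-12 for vtg5 and 2.88e-15 for nots, and other probes read from −14.44 for vtg2 to −11.54 for nots. Females also had more of the secretory regulator xbp1 (−3.29 ± 0.32, adjusted p = 1.46e-08) and of the sterol genes hmgcra (−4.87 ± 0.93) and insig1 (−2.02). Male livers had more hsd11b2 (3.61 ± 0.81) and the transporter abcc4 (2.90 ± 0.58). The androgen synthesis gene hsd17b3 was on every male vehicle array and on no female one, at least 139-fold higher. Oestrogen drives yolk precursor synthesis in the liver of egg-laying vertebrates, and secreting that load calls on folding capacity.

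The remaining male-biased genes of the rule were thrsp (4.96 ± 1.13), hmox1b (4.76 ± 0.80), tmem243a (4.71 ± 0.61), mcm10 (3.72), timp2a (3.65 ± 0.45), ugt5a4 (3.63), dcbld1 (3.45) and ugt5b4 (2.98). The female-biased ones were supt3h (−10.57), vtg7 (−9.77), srfa (−7.69), aanat1 (−7.54) and rtn1a (−6.39), with adjusted p of 0.00806 or less. Other probes read 4.11 for tmem243a and 2.32 for timp2a, but −0.39 for mcm10, 0.43 for dcbld1, 0.24 for supt3h and 0.67 for srfa. Well above background on all arrays of 1 sex and none of the other were 40 genes in males and 11 in females. Beside hsd17b3, the rule named rgra, pcdh10a, rbms2b and foxl1 in males (at least 10.7, 2.75, 2.64 and 1.82-fold) and lrp11 and chrnb1 in females (at least 28.9 and 13.8-fold). Of 3223 called genes 1347 were higher and 1876 lower in males, with 5845 at an unadjusted p under 0.05. The lower share rested on scaling, since quantile normalization gave 2024 higher of 3835 and, with a background model, 2303 of 4300. The median of all genes lay at 0.12. Without Tuebingen male PCB126 replicate 3 5899 genes were called, 3098 higher.

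Ribosomal protein genes were lower in males, 73 of 79 called and all 79 adjusted over the list alone (mean −1.28, adjusted p = 6.73e-25; 0.865 with an estimated correlation, 0.0226 with fry), with rpl6 at −1.62 ± 0.31 and rplp1 at −1.56. The mean of the list lay between −1.26 and −0.16 under the 4 other scalings, so its size depended on scaling. The 75th percentile intensity used for scaling itself differed by sex. Its median was 79.54 over all female arrays and 178 over the males other than Tuebingen male PCB126 replicate 3. How far this shaped the difference was not tested. The vitellogenesis and oestrogen response list was the only one called with an estimated correlation (adjusted p = 1.39e-08, 0.00634 with an estimated correlation). Of its 14 genes 7 were called lower and 2 higher, 9 over the list alone, with a mean of −5.21. Leaving out Tuebingen male PCB126 replicate 3 moved its adjusted p with an estimated correlation to 0.101. Cholesterol biosynthesis (10 called lower, 12 over the list alone; adjusted p = 5.35e-05; 0.865 with an estimated correlation) and the unfolded protein response (14 called lower, 19 over the list alone; 3.6e-07; 0.865 with an estimated correlation) were lower in males, with dnajc3a at −1.81. Male livers were richer in phase II conjugation genes such as sult1st5 (2.70 ± 0.60) and ugt5a1 (3.11), 36 of 41 higher (5 called, 4 over the list alone; adjusted p = 0.00357; 0.865 with an estimated correlation). In the same direction, bile acid metabolism had 4 genes called higher and 1 lower (6 over the list alone; adjusted p = 0.0351; 0.865 with an estimated correlation), with cyp8b1.2 at 2.43. Ovary markers were lower in males (9 called, 11 over the list alone, mean −2.45; adjusted p = 0.000523; 0.865 with an estimated correlation). The egg envelope gene zp3 was called lower and was well above background on 6 of 9 female and 0 of 9 male arrays.

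Against AB livers, the digestive lipase gene cel.2 stood at −9.35 ± 1.01 in Tuebingen and −10.14 ± 1.01 in WIK, and exoc1 at 4.36 ± 0.30 and 4.64 ± 0.30 (6 vehicle fish against 6, both sexes). Adjusted p was 4.16e-07 and 1.07e-07 for cel.2 and 6.17e-11 and 1.35e-11 for exoc1. Tuebingen livers had more transcript of several sterol synthesis genes than AB: lss was higher by 3.86 ± 0.92, hmgcra by 3.72 ± 1.14 and mvda by 3.30 (adjusted p for lss and hmgcra 0.00667 and 0.0353). Chaperone genes of the endoplasmic reticulum followed, with hspa13 at 3.76 ± 0.50, dnajb9b at 3.44 and hyou1 at 2.28. Sterol synthesis genes are generally held down by cholesterol in the cell, which was not measured here. The other genes of the rule for Tuebingen against AB were slc25a10b (4.68 ± 1.35) and il15l (3.55 ± 0.58) upward, and thbs4b (−5.83 ± 0.38), scrn3 (−5.57), apip (−5.55 ± 0.45), dscama (−4.85) and bglap (−4.73) downward. The other probe of slc25a10b read −0.77.

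In the same pair 24 of 25 cholesterol biosynthesis genes were higher in Tuebingen, 16 of them called and 19 adjusted over the list alone (mean 2.06, adjusted p = 1.27e-12; 0.379 with an estimated correlation, 0.00112 with fry). The unfolded protein response had 34 of 36 higher, 8 called and 23 over the list alone (mean 1.28, adjusted p = 3.86e-09; 0.628 with an estimated correlation, 0.0105 with fry). On every array of 1 strain and none of the other were 31 genes in Tuebingen and 13 in AB. The rule named ggact.2, cyp2aa4, psmb8a, rfesd and il1rapl1a, at least 74.6, 20.4, 16.7, 9.78 and 6.44-fold higher in Tuebingen. Of 1791 called genes 812 were higher and 979 lower, with 4214 at an unadjusted p under 0.05, and without Tuebingen male PCB126 replicate 3, through the pooled spread, 3320 were called. With scan day in the model 797 were called, and 1077 without Tuebingen male vehicle replicate 3.

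WIK livers differed from AB by il15l (5.07 ± 0.58), or42d1 (4.85), cyp46a1.3 (4.54), xkr9 (4.00) and bach1b (3.90) upward and by ikbip (−4.65), phyhd1 (−4.63 ± 0.47), apoda.2 (−4.42), lcp2a (−4.34) and them6 (−4.18) downward (6 against 6, both sexes). Proteasome genes lay lower in 36 of 39 cases, 3 called and 5 over the list alone (mean −0.39, adjusted p = 8.57e-06; 0.964 with an estimated correlation), with psmd1 at −1.33 ± 0.32, and the peptide-loading gene tapbp.1 was lower (well above background on 1 of 6 WIK and 6 of 6 AB arrays). Tapasin loads peptides made by the proteasome onto class I molecules, whose gene region differs in content between zebrafish haplotypes. The other probe of cyp46a1.3 read −0.25. Seen on every array of 1 strain alone were 17 genes in WIK and 24 in AB. Those with a symbol were rfesd and or42c3 (at least 9.85 and 3.96-fold higher in WIK) and stap2a, parp14rs1, sarm1 and gpr143 (at least 20.2, 8.15, 2.85 and 2.1-fold lower). Of 1006 called genes 499 were higher and 507 lower, with 3256 at an unadjusted p under 0.05, and leaving out Tuebingen male PCB126 replicate 3 gave 2134. With scan day in the model 309 were called.

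Against Tuebingen, WIK livers had less transcript of sterol synthesis genes: acat2 read −5.13 ± 0.62, lss −4.16 ± 0.92, and the chaperone gene calr −4.92 ± 1.19, whose other probes averaged −1.55 (6 against 6, both sexes; adjusted p for acat2 2.27e-06). The peptide-loading gene tapbp.1 was well above background on 1 of 6 WIK and 6 of 6 Tuebingen arrays. The class I gene mhc1uba was on every Tuebingen array and no WIK array, at least 324-fold lower. The cytokine feedback gene cisha was higher by 5.40 ± 1.03 and the bile acid hormone gene fgf19 by 3.67 ± 0.87 (adjusted p = 0.000882 and 0.00603). Cholesterol biosynthesis had 18 genes called lower and 19 over the list alone (mean −2.25, adjusted p = 1.02e-14; 0.195 with an estimated correlation, 0.000237 with fry). The unfolded protein response had 20 and 23 (mean −1.71, adjusted p = 7.54e-14; 0.195 with an estimated correlation), with hyou1 at −2.96. Antigen presentation had 7 called lower and 8 over the list alone (adjusted p = 1.02e-05; 0.731 with an estimated correlation), and proteasome genes 21 and 28 (mean −0.73, adjusted p = 3.35e-14; 0.628 with an estimated correlation). Growth and thyroid axis genes were higher, 6 called and 6 over the list alone (adjusted p = 0.00293; 0.982 with an estimated correlation), with thraa at 1.78 ± 0.33 and igfbp1b at 3.28.

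The other genes of the rule in that pair were thbs4b (5.10 ± 0.38), apip (4.75 ± 0.45), gjb1a (4.28) and oclna (3.69, other probe 0.51) upward and cptp (−4.92), phyhd1 (−4.49) and snu13a (−4.30) downward. On 1 side alone were 12 genes in WIK and 30 in Tuebingen. Beside mhc1uba, the rule named cacng6a, fbp2, oc90 and or42c3 in WIK (at least 46.7, 17.9, 12.5 and 5.12-fold) and sat2a.2, ggact.2, psmb8a and parp14rs1 in Tuebingen (at least 149, 68.2, 15.2 and 7.64-fold). The 2116 called genes were 1007 higher and 1109 lower, with 4529 at an unadjusted p under 0.05 and a median of all genes of 0.12. Median centring gave 731 higher of 2084, and leaving out Tuebingen male PCB126 replicate 3 gave 3814. High sterol gene transcripts and low cisha in vehicle Tuebingen fish and their opposite shift on exposure rest on the same 6 vehicle fish, so the 2 results are not independent.

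The sample of 1 array labelled as an exposed male liver carried egg genes. On Tuebingen male PCB126 replicate 3 the egg envelope genes zp2.1, zp2.3, zp2.2 and zp3 read 6.93, 6.92, 6.62 and 6.31 and cldnd 6.67, where zp2.1 was at most −2.16 on every other male array. The hepatocyte gene fabp10a read 6.20 where every other array had at least 9.98. These genes were chosen after their values were seen. The 24 ovary markers averaged 4.77 on this array, against −3.93 to −2.81 in the other males and up to 4.8 in females. Hepatocyte markers averaged 2.82 against at least 7.49 elsewhere. Its yolk gene vtg2 read 5.93, between other males and females, whose lowest value was 11.17. It correlated with its group mates at 0.57 to 0.58, where all other arrays reached at least 0.90, and its 75th percentile intensity was 1138 against 43.41 to 411.5. This array stayed in all comparisons because the choice of arrays had been made before the data were examined.

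**Figure D4:**
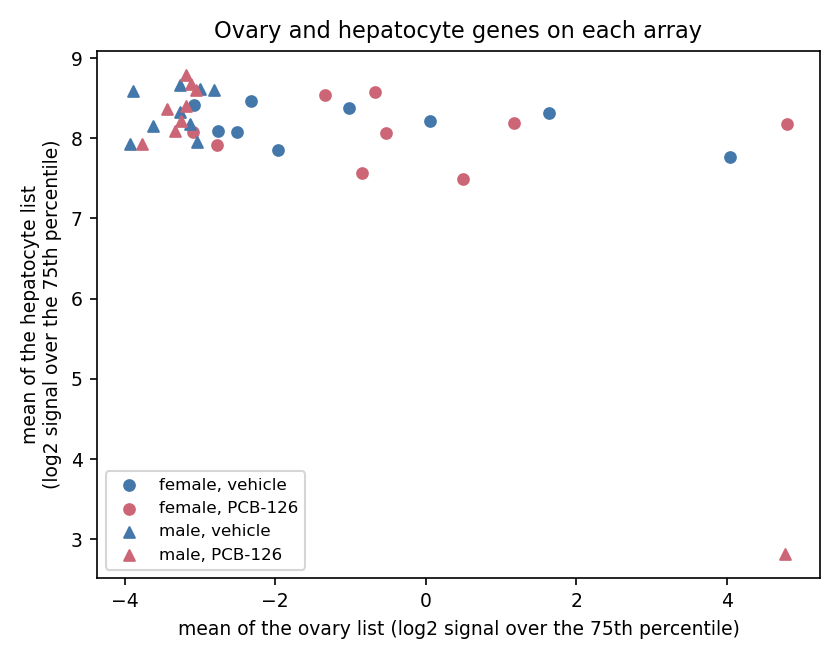
Mean of 24 ovary markers against the mean of the hepatocyte markers on each array, by sex and treatment. Tuebingen male PCB126 replicate 3 lies with the highest females in ovary markers and below every other array in hepatocyte markers.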

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

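The tests of the array unlike its group, of other probes, of the slide and of cyp1a were chosen only after those results were seen.

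TC381339 stood out because its response to exposure differed between the sexes: adjusted p = 0.0199, from 1 probe that was well above background on 6 vehicle and 1 exposed male arrays and on no female array. The sex difference of cyp2k6 varied between strains (adjusted p = 0.0194; 1 probe), with vehicle males well above background in Tuebingen alone (mean −2.12). That of slc2a11b did too (adjusted p = 0.0319; 1 probe), with 3 of 3 Tuebingen males, 1 of 3 Tuebingen females, 2 of 3 WIK females and no other vehicle fish well above background.

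Tuebingen male PCB126 replicate 3 had egg genes at the level of the highest females and the least hepatocyte signal of all 36 arrays, with the egg envelope genes zp2.1, zp2.3 and zp3 at 6.93, 6.92 and 6.31. A failed hybridization was argued against by 25201 probes well above background, inside the range of the other arrays (13770 to 31382), and by a spike-in slope of 0.952 (others 0.863 to 1.005). Neither value measures how intact the liver RNA was, so degraded RNA was not tested. The array carried a quality flag and 77 outlier spots, and the other arrays with its scan time, also flagged, had 47 and 106. A swap with a female sample of this set was argued against because 0 female arrays had vtg2 as low as a male (females at least 11.17, other males at most 4.63, this array 5.93). Ovary RNA in this sample had what it needed: the 24 ovary markers, 12 of which were well above background in at least 50% of the other male arrays, averaged 4.773 against at most −2.81 in other males, and 21 of them were higher than in every other male. Whether this may be ovary tissue taken with or instead of the liver, a fish with both kinds of germ tissue, or a sample from outside the set stays open, and no biological explanation was tested.

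Genes that fell most after exposure, such as cdc73, med17, stk17a and smim10l3, did so on 1 probe. Scan day alone as the cause was argued against for the 100 genes most clearly lower on 22 arrays, 11 of them from the 3 days with both treatments. These genes had a median of −0.941 when 12 other arrays were compared within day, strain and sex (−1.26, −0.56 and −1.05 on the 3 days; 80 of 100 lower; all genes −0.02). Each stratum there compared 1 exposed with 1 vehicle array from different slides, so slide could give the same fall. Genes that vary together are also not separate tests. With scan day in the model 0 genes were called in all fish. A signal of single probes was argued against for falls of up to 1.5, where other probes of 19 genes had a median of −0.587 against −0.88, but not for larger falls, where 21 genes had −0.095 against −2.08 and 2 of them moved by at least 50% of the called probe. These 56 larger falls also varied together between fish of the same group (median correlation 0.64, against 0.08 for the smaller falls and 0.005 for random genes), so they may reflect 1 shared property of the samples rather than 56 responses. The slide could not be told apart from exposure because 1 of 12 slides held both treatments.

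The canonical receptor target cyp1a was not called in any exposure comparison. Of the alternatives that gave a value for cyp1a, which leave out the authors' matrix and the minimum fold, it was called only with array weights, higher in Tuebingen (0.808, adjusted p = 0.0255). A ceiling of the signal was argued against by 0 saturated spots and by the dimmer probes, whose highest change without Tuebingen male PCB126 replicate 3 was 0.225 ± 0.17, beside 0.32 ± 0.17 on the brightest. That array hiding a rise could not be told apart from no rise: without it cyp1a read 0.32 with an interval of −0.02 to 0.66, which includes both 0 and a 1.5-fold rise. The dose of receptor agonist that reached the liver and the time of sampling remain untested biological explanations.

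Random splits of the fish between treatments, or between sexes or strains, 100 per comparison and within the other factors, asked whether chance could give as many called genes. Fewer than 5 of 100 splits gave as many for exposure in all fish (165 called; 1 of 100 splits gave as many, the real one; highest other 67), in AB (5; 1; 4), in females (8; 1; 1) and in males (2; 4; 4). The same held for sex (3223; 1; 1), Tuebingen against AB (1791; 1; 1), WIK against AB (1006; 1; 2) and WIK against Tuebingen (2116; 1; 1). The bound was not corrected for the 13 comparisons, and in AB and males another split came close to or passed the real count, so chance was not excluded there. It could not be excluded either for WIK (2; 17; 6), sex by exposure (1; 8; 2) or Tuebingen (64; 5; 424). For strain by sex 2 of 100 splits gave at least the 2 called, but 1 of them gave 17, and leaving out single arrays moved that count from 0 (Tuebingen female vehicle 1) to 23 (Tuebingen male PCB126 3). Other splits reached 424 against 64 in Tuebingen, 17 against 2 for strain by sex, 6 against 2 in WIK and 4 against 2 in males. Why they did so was not tested. For strain by exposure the count was 0, so all 100 splits gave as many by construction (highest other 4) and the splits decide nothing. The splits took no account of slide, which largely followed treatment, or of scan day, which partly did, and with scan day in the model the all-fish count was 0. Leaving out Tuebingen male PCB126 replicate 3, fewer than 5 of 100 splits gave as many in all fish (369; 1; 73), AB (100; 1; 14) and females (181; 1; 64).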

How the results depend on the processing

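Tests that combine leaving out Tuebingen male PCB126 replicate 3 with a second change, and list tests without that array or with scan day, were chosen only after the data were seen. Counts are of called genes, and for each one given here that lay more than 1.5 times from its main value the cause was not tested unless stated. Main counts were 165 in all fish, 5 in AB, 64 in Tuebingen, 2 in WIK, 8 in females, 2 in males, 3223 for sex, 1791 for Tuebingen against AB, 1006 for WIK against AB, 2116 for WIK against Tuebingen, 1 for sex by exposure, 0 for strain by exposure and 2 for strain by sex. Signal over background limits the genes: 31.6 to 72 percent of probes were well above background per array.

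With normexp (offset 50) and the 75th percentile, counts were 0 in Tuebingen, 0 in WIK, 58 in all fish (8 higher), 3 in females (2 higher), 6 in males, 470, 333 and 568 for the strain pairs (Tuebingen against AB, WIK against AB, WIK against Tuebingen), 1506 for sex, and 0, 1 and 0 for the interactions (sex by exposure, strain by exposure, strain by sex). With normexp (offset 50) and quantile normalization they were 21 in AB, 196 in Tuebingen, 7 in WIK (4 higher), 272 in all fish, 27 in females (15 higher), 42 in males (7 higher), and 2, 10 and 7 for the interactions. Quantile normalization gave 131 in Tuebingen, 13 in females (8 higher), 5 in males (2 higher) and 1 for strain by sex, with 2 of 6 higher in AB. Median centring gave 99 in Tuebingen, 0 in WIK and 2 for sex by exposure, with 102 of 199 higher in all fish and 4 of 4 in AB. The authors' series matrix, with about 6 in 10 probes, gave 246 in Tuebingen, 1 in WIK, 38 in females (9 higher), 31 in males (8 higher) and 0 for strain by sex, with 5 of 7 higher in AB. These scalings moved the median of all genes in Tuebingen to −0.34 (normexp and 75th percentile), −0.15 (quantile) and −0.10 (median centring), and between the sexes to −0.17, 0.19 and 0.13.

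Of 520 named gene results, quantile normalization kept 481 on their side of the threshold, median centring 496, normexp with quantile 461 and normexp with the 75th percentile 328. Reversed with normexp and the 75th percentile were ncoa2 (−0.221), abcg2c (−0.003), cyp8b1.3 (−0.118), mxe (−0.040), tefb (−0.179), insrb (−0.181), kdr (−0.148) and myhz1.1 (−0.060) for sex, where the main values were positive, and spata17 (−0.073) for WIK against Tuebingen. hsp90ab1, lower in males in the main result, read 0.164 with quantile normalization, 0.137 with normexp and quantile, and 0.166 with quantile normalization without Tuebingen male PCB126 replicate 3.

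Without a filter on dim probes, counts were 2 in AB, 105 in all fish and 7994 for sex. Probes well above background on all 36 arrays gave 11 in AB, 1 in WIK, 0 in males, 916, 295 and 1261 for the strain pairs, 1579 for sex and 0 for strain by sex, with fewer genes tested by construction. The mean over the gene's probes gave 8 in AB, 5 in females and 1 in males, and cyp7a1, called higher in WIK than in Tuebingen, read −0.155. Every probe tested on its own gave 13 in AB, 2823, 1567 and 3402 for the strain pairs and 5107 for sex, with more features tested by construction. Keeping spots called outliers changed no count by over 1.5 times.

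A minimum fold of 2 left 106 in all fish; this setting has no value for the interactions with strain, and a model without interactions was fitted for all fish alone. A trend in the spread with robust fitting gave 8 in AB and 0 for sex by exposure. Fitting only the groups compared gave 0 in AB, 0 in Tuebingen, 0 in WIK, 82 in females, 0 in males, 2840, 2204 and 3269 for the strain pairs, 6127 for sex and 13 for strain by sex. Array weights, whose fit did not converge, gave Tuebingen male PCB126 replicate 3 a weight of 0.0325 (others 0.336 to 18.5). With them counts were 372 in AB, 2352 in Tuebingen, 226 in WIK, 1861 in all fish, 265 in females, 2674 in males, 4503, 3025 and 5211 for the strain pairs, 7720 for sex, and 6, 685 and 690 for the interactions, and cyp1a in Tuebingen read 0.808 and was called (adjusted p = 0.0255), as under no other alternative that gave a value for it (the authors' matrix and the minimum fold gave none).

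Scan date as a fixed block gave 0 in AB, 34 in Tuebingen, 1 in WIK, 0 in all fish, 4 in females and 0 in males, and 797 and 309 for Tuebingen and WIK against AB. Slide as a fixed block gave 0 in AB, 0 in Tuebingen, 0 in WIK, 0 in all fish, 0 in females and 0 in males, 74, 21 and 1319 for the strain pairs, 0 for sex by exposure and 0 for strain by sex; treatment and slide overlap almost fully, so few arrays inform it. With it dnajb1a in all fish read −0.030 and hmgcra for Tuebingen against AB −0.999. Slide as a random block (correlation 0.112) gave 2 in AB, 11 in Tuebingen, 63 in all fish, 1 in males and 2 for sex by exposure. The individual number as a replicate block gave 10 in AB and 1 for strain by exposure; pairs of arrays with the same number had a median correlation of 0.028 against −0.015 for others, so the numbers do not pair the fish. Of the 520 named gene results, 376 held with scan date, 299 with slide as fixed, 478 with slide as random and 506 with the replicate block.

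Leaving out 1 array moved the all-fish count between 88 and 440. It was 250 without AB female PCB126 replicate 1, 343, 440 and 369 without Tuebingen male PCB126 replicates 1, 2 and 3, and 88 to 109 without each of WIK female vehicle 3 (88), AB female PCB126 2 (94), Tuebingen female vehicle 3 (95), AB male vehicle 1 (96), WIK male vehicle 3 (97), AB male PCB126 3 (100), WIK female PCB126 2 (100), WIK male vehicle 1 (100), WIK male PCB126 2 (104), AB male PCB126 2 (107), Tuebingen male vehicle 2 (107) and Tuebingen female PCB126 2 (109). For Tuebingen it ran from 3 to 1391: 3 and 100 without Tuebingen female vehicle replicates 3 and 2, 8 and 15 without female PCB126 replicates 1 and 2, 10, 38 and 13 without male vehicle replicates 1, 2 and 3, and 555 and 1391 without male PCB126 replicates 1 and 2. For AB it ran from 1 (without AB female PCB126 2, AB male PCB126 1 or 2, or AB male vehicle 1 or 3) to 100 (Tuebingen male PCB126 3), with 22 without AB female PCB126 1. For WIK it ran from 0 (WIK male PCB126 2) to 17 (Tuebingen male PCB126 3), for females from 6 (AB female vehicle 2) to 181 (Tuebingen male PCB126 3), with 16 without AB female PCB126 3 and 14 without Tuebingen female vehicle 2, and for males from 0 (AB male PCB126 2 and 3, AB male vehicle 1 and 3, Tuebingen male vehicle 1 and 3, WIK male vehicle 1) to 146 (Tuebingen male PCB126 2).

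Sex ran from 2447 (without WIK female vehicle 1) to 5899, Tuebingen against AB from 1077 (Tuebingen male vehicle 3) to 3320, WIK against AB from 718 (AB male vehicle 2) to 2134 and WIK against Tuebingen from 1172 (Tuebingen male vehicle 3) to 3814, each highest without Tuebingen male PCB126 replicate 3. Sex by exposure ran from 0 to 3 (3 without Tuebingen male PCB126 2), strain by exposure from 0 to 6 (6 without Tuebingen female vehicle 2) and strain by sex from 0 (Tuebingen female vehicle 1) to 23 (Tuebingen male PCB126 3), with 19 without Tuebingen female vehicle 2. Over 18720 fits of a named gene with an array left out, 17335 kept their side of the threshold and 0 reversed; where this left 2 fish in a group, they were taken to vary like the other groups.

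With scan date as a fixed block and Tuebingen male PCB126 replicate 3 left out, counts were 0 in AB, 42 in Tuebingen, 1 in WIK, 194 in females, 0 in males, 3727 for WIK against Tuebingen, 6454 for sex, 2 for sex by exposure and 8 for strain by sex. Without it and with slide as a random block (correlation 0.154), they were 43 in AB, 159 in females, 2984, 1635 and 4494 for the strain pairs, 6867 for sex, 2 for sex by exposure and 98 for strain by sex. Without it and with quantile normalization, they were 107 in AB, 114 in Tuebingen, 15 in WIK, 387 in all fish, 229 in females, 14 in males, 3189, 2126 and 3628 for the strain pairs, 6067 for sex, 1 for strain by exposure and 14 for strain by sex. Without it and with the individual number as a replicate block, they were 94 in AB, 18 in WIK, 426 in all fish, 192 in females, 9 in males, 3417, 2182 and 3911 for the strain pairs, 6058 for sex, 3 for strain by exposure and 6 for strain by sex. The array left out also raised the counts of comparisons it had no part in, because it widens the pooled spread.

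Of 41 gene lists, the numbers called with the preset correlation were 12 in AB, 19 in Tuebingen, 5 in WIK, 13 in all fish, 6 in females, 14 in males, 3, 1 and 6 for the strain pairs and 14 for sex. With an estimated correlation they were 0 in AB, 0 in Tuebingen, 0 in WIK, 0 in all fish, 0 in females, 0 in males, 0, 0 and 0 for the strain pairs and 1 for sex. With fry they were 0 in AB, 1 in Tuebingen, 0 in WIK, 0 in all fish, 0 in females, 0 in males, 0 for WIK against AB and 4 for sex, and without Tuebingen male PCB126 replicate 3 fry called 27 for sex, 1 each in AB, in all fish and in females, and none in Tuebingen, in WIK or in males. For WIK against Tuebingen fry called 4, and 5 without that array, and for Tuebingen against AB 2 and 3. With scan date the called lists were 9 in WIK, 5 for Tuebingen against AB and 3 for WIK against AB. Without Tuebingen male PCB126 replicate 3 they were 4 in Tuebingen, 6 in males and 2 for WIK against AB, and with scan date as well 8 in all fish, 4 in Tuebingen, 6 in males, 6 for Tuebingen against AB and 4 for WIK against AB. Without that array and with an estimated correlation they were 1 in AB, 1 in females, and 0 in all fish, Tuebingen, WIK, males, sex and every strain pair.

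Ribosomal protein genes had no stable direction after exposure. Without Tuebingen male PCB126 replicate 3 the list turned upward in Tuebingen (adjusted p = 1.26e-06; up to 0.811 over the alternatives) and in males (0.000968; up to 0.869), and with scan date it turned downward in AB (6.27e-07, and 0.00206 without that array; up to 0.996). Its mean also changed sign in AB under 1 of the 4 other scalings, and in Tuebingen and in males under quantile normalization without that array. Acinar pancreas markers, lower in all exposed fish in the main result, turned higher with scan date and without that array (adjusted p = 0.0142; up to 0.945). The means of the other lists called in all fish kept their sign under the 4 other scalings, and under quantile normalization without that array.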

Other observations

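Clock genes gave 3 calls with exposure and no list call. Beside nfil3-5 and bmal1a, which rose, and dbpb, which fell, the clock repressor nr1d1 read −1.38 ± 0.42 with the same sign in all 6 strata (adjusted p = 0.123). The clock list had 16 of 38 genes higher, 2 called higher and 1 lower, and its mean (−0.09) and its camera test (upward, adjusted p = 0.611) differed in sign. Replication gene mcm6 fell by 1.72 ± 0.42 in all 6 strata (adjusted p = 0.0454; other probe −1.56), and the glutathione gene gclm rose by 0.82 ± 0.18 in 5 (adjusted p = 0.0227), though its other probe read −0.05. Single members of several lists also differed by sex in vehicle fish: males had less fads2 (−3.51 ± 0.49, adjusted p = 7.09e-06) and mid1ip1b (−4.13 ± 0.56, 4.73e-06) and more cyp3a65 (2.6 ± 0.72, 0.0134), apoeb (2.00 ± 0.54, 0.0106) and cry1b (1.47 ± 0.48, 0.0331), each in all 3 strains.

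Egg genes were also present in some female livers: the mean of the 24 ovary markers ran from −3.09 to 4.8 over the 18 female arrays and lay over 0 on 6 of them, while their hepatocyte marker mean was at least 7.49. The mean of 26 acinar pancreas markers ran from 1.02 to 8.05 and that of 23 intestine markers from −1.99 to 4.87 over the 35 arrays other than Tuebingen male PCB126 replicate 3, on which they read −3.00 and −5.36. The profiles closest to that array were WIK female PCB126 replicate 1, AB female vehicle replicate 3 and Tuebingen female PCB126 replicate 2 (correlation 0.711, 0.702 and 0.636), and in the authors' matrix it correlated with its group at 0.632 to 0.633, where all others reached at least 0.94.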
